A study of Mus musculus with 6 samples.

How the data were processed

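Total RNA from mouse prefrontal cortex was labelled with Cy3 and Cy5 and hybridised to in-house printed arrays, per the labels' protocols. The 6 slides hold 3 biological pairs, each a direct comparison of collagen and control RNA with the dyes exchanged on the other slide, per the labels. The spot intensity in either channel was deposited already corrected for local background, with area, saturation, background and flags, per the file headers. The image analysis program is not given in the sources used here. The 16 scanner files hold 3 scans of each slide of pairs 1 and 2, and 2 scans of each slide of pair 3. No normalization is recorded in them. A series-wide value table was deposited as well, and its values were treated as a score because neither the log base nor the normalization is stated.

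Spots were matched to probe numbers by grid order (metarow, metacolumn, row, column). In that order the value table correlated with the log2 channel ratios at r between 0.60 and 0.88 in size, against 0.33 at most in size for the other of 384 orders tried on each slide. Column medians of the value table were -0.0037 and -0.0015 in pair 1, 0.0040 and 0.00092 in pair 2, and 0.0025 and 0.0030 in pair 3, so it is centred near 0. The table was found to run as channel B over A on slides with collagen RNA in Cy5 and as A over B on the others. Its scale, and which arm it puts on top, stay unknown. The platform annotation lists 9078 probes, of which 9066 have 1 gene symbol and 12 several, while 1002 probes are unnamed here. By gene identifier, 8977 probes were matched to the RefSeq annotation and 0 symbols changed. Probes without exactly 1 symbol were tested but not named. No genome build is named in the files, so no coordinates are given.

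Intensities were divided by spot area, and the log2 ratio of channel B over A was normalized within each scan by loess (span 0.3, 4 iterations). Scans of a slide were averaged, ratios were turned to collagen over control, and both slides of a pair were averaged, so that a constant dye effect cancels. The design written before the data were examined named normexp with an offset of 50 where background is given. Because the deposited intensities were found to be background-corrected already, they were used as deposited, and normexp on the rebuilt foreground became an added alternative. Plain subtraction of background is identical to the setting used. Spots with a value of 0, which the image analysis did not accept, were left out, and saturated spots were kept. Spots with a saturation factor below 1 made up between 3.53% and 7.47% of each slide's last scan.

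A probe was kept where the foreground exceeded 1.5 times the background in at least 1 channel on at least 3 slides (9998 probes), and where every pair had a value on both slides. Of several probes of a gene the brightest stood for it. For 80 genes several probes could be tested, and in 40 of them the probes had opposite signs. The test was limma (version 3.58.1, R 4.3.3), lmFit and eBayes on 3 pair values against 0, 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with camera (preset correlation 0.01, at least 5 tested genes), with an estimated correlation and with fry. Of 687 list genes 352 were on the array and 200 tested. The dye effect was tested with limma on the mean of the unturned ratios of a pair's slides. The slide numbers fall together with the pairs, so the pair is the only batch that they show. Pairing comes from the labels, where both slides of a pair carry the same RNAs. Deviations of the unturned ratios from the orientation mean correlated within pairs at 0.06, 0.40 and 0.21. With the dyes exchanged, shared RNA differences would give negative values, so these values do not bear out a pairing with the dyes exchanged. With the slides of the other pairs the mean was lower, at -0.02, -0.19 and -0.12. Deviations from a mean lean below 0 between pairs by construction, so this contrast is partly built in. The pairs are labelled as biological replicates. The limma p-values of genes rest on the spread between them, moderated by a variance shared over all genes (prior degrees of freedom 9.51). Camera with the preset correlation compares a list with the other genes. Its p-values therefore rest on the spread across genes and do not measure the spread between pairs.

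Genes were named by this rule: the 15 largest rises and falls past the threshold with one sign in all pairs; where fewer than 10 passed in a direction, those with the smallest unadjusted p and one sign on all 6 slides, up to 10; up to 2 members of each list at an unadjusted p under 0.05 (4 for a list that passed); and 13 fixed genes where measured.

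The procedure was tested on simulated slides of 4815 genes, for the collagen versus control comparison, with 200 changed genes and a dye effect. Of 50 genes changed by 0.5 on the log2 scale 66.0% were recovered, and all of those changed by 1, 1.5 or 2 (100% each). Of the calls 6.15% were false. Unshifted lists reached an unadjusted p under 0.05 in camera in 1.51% of 199 cases. Their genes were simulated independently, so this share does not cover lists whose genes move together. Among the real lists the estimated correlation was 0.53 for cytokines and chemokines and 0.10 for oxidative phosphorylation. The simulation has even spread between pairs and no slide faults, which the real slides had. Its slides vary independently, while turned ratios of the real slides of a pair correlated negatively. Its many genes changed by 1 or more also ease the adjusted threshold for those changed by 0.5. In the real data Wdr82, at 0.51, had an adjusted p of 0.997 in limma. The recovered shares therefore hold for the simulated setting only. Alternatives covered background correction, normalization, filters, scans, replicate block, probe choice, variance model, the value table and leaving out each pair. Changes of filter, probe choice, variance model or replicate block left the log2 ratios of named genes unchanged, so no direction could turn there. Of 34 named genes, 19 had a value on the first scan, 18 on the last scan and 19 in the value table.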

Results

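Gene expression was measured in the prefrontal cortex of male C57Bl/6 mice, an inbred laboratory strain, on in-house printed 2-colour oligonucleotide arrays. The mice were 8 weeks old. The collagen arm received 100 ul of type II collagen, the main collagen of cartilage, in 100 ul of complete Freund's adjuvant, an oil with killed mycobacteria that provokes inflammation. The control arm received 200 ul of the adjuvant alone, and both arms were given lipopolysaccharide, a bacterial cell wall component, at day 24. The controls were therefore immune-stimulated animals, and the arms differed in the volume of adjuvant as well as in collagen. The time of death in the labels is ambiguous and is not used here. RNA of the arms was hybridised directly against each other in 3 biological pairs, and each pair was run on 2 slides with the dyes exchanged, giving 6 slides. A pair counted as 1 replicate (n = 3). Whether a pair held 1 mouse or a pool per arm is not stated in the labels used here.

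Each slide carried 10080 spots. Both channels gave an accepted signal on 9312 spots of pair 1 with collagen RNA in Cy5 and 7878 with collagen RNA in Cy3. The same counts were 9670 and 9711 in pair 2, and 6911 and 7660 in pair 3. Median background-corrected signal over local background lay between 0.893 and 2.91 in channel A and between 1.58 and 4.03 in channel B. A value on both slides of every pair was present for 4815 genes. The number of arrays limits the precision: the median standard error of a log2 ratio was 0.12. All ratios are given as collagen over control. This direction is likely and not certain: the files name the channels A and B, and channel B was read as Cy5. The basis is only the order of the channels, since the labels list Cy3 first and Cy5 second on every slide. The authors' value table runs as channel B over A where collagen RNA carried Cy5 and as A over B on the exchanged slides, which shows slides turned one way but not which arm it puts on top. Every sign below turns if the channels were named the other way.

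The first question was which genes differ in the prefrontal cortex between collagen-injected and control mice. No gene passed the test (0 of 4815, limma, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 216 genes, 102 of them higher and 114 lower, against 240.75 expected by chance. The smallest adjusted p in limma was 0.403. Of the tested genes, 99.0% had a mean ratio within 0.5 on the log2 scale. The 6 genes beyond 1 on that scale all lay in the first spot column of the slides, where 1 slide of pair 3 had extreme ratios. No probe was seen with the RNA of one arm on all 6 slides and with that of the other arm on none (0 in either direction).

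The genes below were named by a rule fixed before the data were examined, as those with the smallest unadjusted p among genes of one sign on all 6 slides. None passed the test, and each had an adjusted p of 0.997 in limma. Toward collagen, Wdr82, a subunit of a histone H3 lysine methyltransferase complex, had a log2 ratio of 0.51 ± 0.19 (SD, n = 3). Map1b, a microtubule-associated protein of growing neurites, had 0.43 ± 0.27 (SD, n = 3). In the authors' value table, whose log base is not stated, 3142 genes could be tested. Wdr82 and Map1b were the only genes to pass there in the same limma test (2 genes, each with an adjusted p of 0.0415). Both were higher with channel B read as Cy5. The size of its values relative to the log2 ratios was 0.19 on the pair 3 slide with collagen RNA in Cy3, against 0.56 to 0.77 on the others. On that slide Map1b had a log2 ratio of 1.35, against 0.02 on its partner. The homeobox genes Dlx3 and Gsx1 had 0.44 ± 0.14 and 0.37 ± 0.06 (SD, n = 3). The topoisomerase genes Top2a and Top1 had 0.35 ± 0.13 and 0.33 ± 0.17 (SD, n = 3). Ddx6, an RNA helicase of processing bodies, had 0.41 ± 0.25, and Rita1, a regulator of Notch signalling, had 0.42 ± 0.28 (SD, n = 3). Cbx3, a heterochromatin protein, had 0.30 ± 0.02, and Foxp3, the transcription factor of regulatory T cells, had 0.33 ± 0.08 (SD, n = 3). Their sizes and order depended on the background method: with normexp, Top1 had 1.08, Foxp3 1.06, Gsx1 0.92 and Map1b 0.80, against 0.68 for Wdr82.

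Toward control, Mag, myelin-associated glycoprotein, had a log2 ratio of -0.38 ± 0.21 (SD, n = 3). Phpt1, a histidine phosphatase, and Gas1, a growth-arrest membrane protein, each had -0.28, with SDs of 0.15 and 0.20 (n = 3). The centrosomal gene Cep250 and the cullin gene Cul7 each had -0.28, with an SD of 0.09 (n = 3). Ulk1, a kinase that starts autophagy, had -0.27 ± 0.07, and the peptidase gene Dpp4 had -0.26, with pair values of -0.26, -0.27 and -0.26. Dlst and Pgam5, which encode mitochondrial proteins, had -0.26 ± 0.03 and -0.25 ± 0.07 (SD, n = 3). Plxnb2, a semaphorin receptor, had -0.25 ± 0.09 (SD, n = 3). With normexp, Cep250 had -0.83, Dlst and Ulk1 -0.77 each, Dpp4 -0.66 and Cul7 -0.63, against -0.62 for Mag. One sign on all 6 slides was shown by 103 genes, 57 higher and 46 lower, against 150 expected if the signs of slides were independent. The count of genes past the threshold depended on which pair was left out. It was 40 without pair 2, of which 33 lay in the first spot column, and 14 without pair 3.

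**Figure D1:**
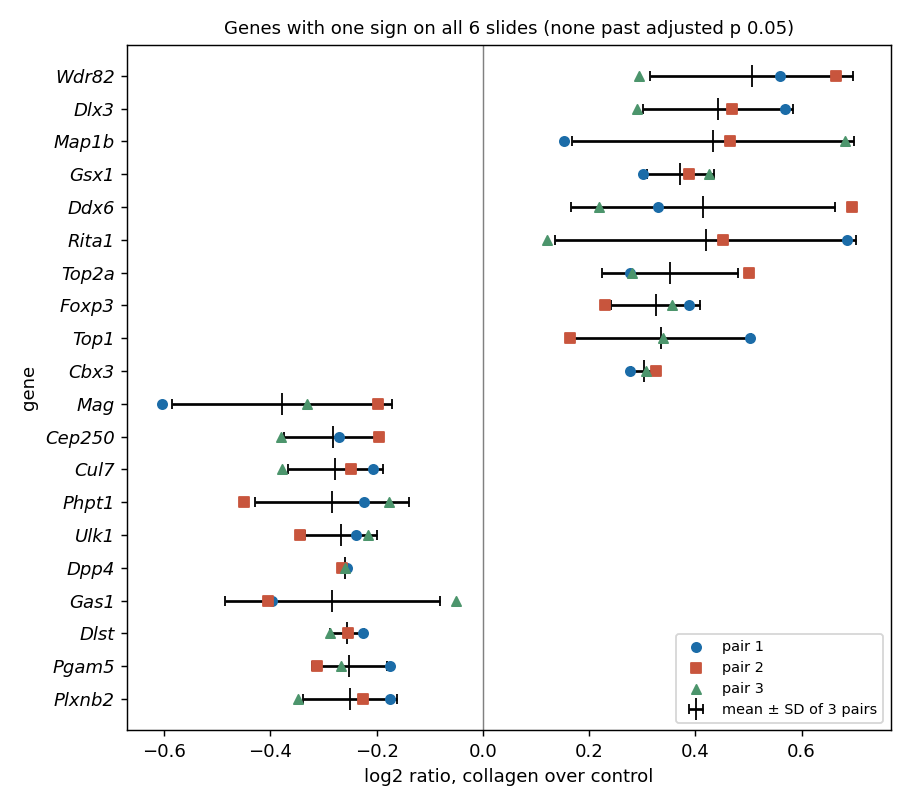
Log2 ratio of collagen over control (x axis) of 20 named genes (y axis). Points are the 3 biological pairs, each the mean of 2 dye-exchanged slides, and bars are the mean ± SD. As plotted, without normexp, the means run from -0.38 (Mag) to 0.51 (Wdr82), with normexp from -0.83 (Cep250) to 1.08 (Top1), and no gene passed the test with either.

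The second question was whether groups of related genes moved together. Of 35 gene lists fixed before the data were examined, 24 had at least 5 tested genes, and none passed camera, limma's test of a list against all other genes (0 of 24 at an adjusted p under 0.05, 3 at an unadjusted p under 0.05). None passed with an estimated correlation either (0 lists), nor with fry (0 lists). Of the 200 list genes tested, none passed over all genes, and 3 passed adjusted over the list alone. The adjustment over a list alone does not correct for the number of lists.

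Immediate early genes, which neurons switch on within minutes of activity, stood nearest to the threshold together with the myelin genes, at the same adjusted p. Of 9 tested, 8 had ratios above 0, with a mean log2 ratio of 0.15 ± 0.06 (SD of pair means, n = 3) and a median of 0.20. The camera adjusted p was 0.0534, and the adjusted p = 0.824 with an estimated correlation. Fos had 0.26 ± 0.34 and Bdnf, a neurotrophin, 0.24 ± 0.45 (SD, n = 3), so both spreads exceeded the means. Only Dusp1, a phosphatase gene, had one sign in all 3 pairs, at 0.03. The list's median was -0.07 on slides with collagen RNA in Cy5 and 0.48 on those with collagen RNA in Cy3. The list passed in camera after print-tip loess, with an adjusted p of 0.0105, and after scaling between slides (0.0238). It also passed with an intensity trend in the prior variance (0.0435) and without the first spot column (0.0399). It did not pass under the other alternatives. Among these, the camera adjusted p was 0.23 after median centring, 0.60 on the first scan and 0.15 on the last scan. It was 0.24 without pair 2 and 0.36 without pair 3.

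Oligodendrocyte and myelin genes lay toward control, with 4 of 5 tested genes below 0 and a mean of -0.16 ± 0.05 (SD of pair means, n = 3). The camera adjusted p was 0.0534, and the adjusted p = 0.824 with an estimated correlation. Mag, given above, and Pllp, a proteolipid of myelin with -0.31 ± 0.09 (SD, n = 3), were the 2 members that passed limma's test adjusted over the list alone, each at an adjusted p of 0.0388. Pllp had opposite signs on the slides of either orientation in every pair. The other 3 members, Mal, Sox10 and Olig2, had -0.06, -0.06 and 0.00. The list passed in camera without background correction, with an adjusted p of 0.0212, and without the first spot column (0.0399). It did not pass under the other alternatives that tested it. Among these, the camera adjusted p was 0.25 after print-tip loess, 0.28 after median centring and 0.34 without pair 1.

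Genes of oxidative phosphorylation, the mitochondrial respiratory chain, lay toward collagen in 12 of 14 cases, with a mean of 0.11 ± 0.08 (SD of pair means, n = 3). The camera adjusted p was 0.063, and the adjusted p = 0.824 with an estimated correlation. Ndufa4 had 0.24 and Cox6c 0.22, while Uqcrc1 had -0.22, and none of the 14 passed over the list alone. The list passed with an intensity trend in the prior variance, with a camera adjusted p of 0.0435. It did not pass under the other alternatives. Among these, the camera adjusted p was 0.30 without background correction, 0.63 after median centring, 0.47 after print-tip loess and 0.37 after scaling between slides. Ribosomal protein genes were above 0 in 10 of 11 cases, with a mean of 0.06 ± 0.04 (SD of pair means, n = 3), and did not pass (camera adjusted p 0.406).

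Genes of immunity and inflammation gave no call. Interferon response genes were above 0 in 5 of 5 cases, with a mean of 0.10 ± 0.10 (SD of pair means) and a camera adjusted p of 0.406. Among them Gbp2, an interferon-induced GTPase, had 0.29 ± 0.31 (SD, n = 3). Cytokines and chemokines were above 0 in 6 of 7 cases, with a mean of 0.06 ± 0.15 (camera adjusted p 0.659). The cytokine gene Il1b had 0.03 ± 0.21 (SD, n = 3), with its sign turned after print-tip loess, in the authors' value table and without pair 3. Genes of NF-kB and Toll-like receptor signalling had a mean of 0.03 ± 0.08 (camera adjusted p 0.719), and eicosanoid and prostaglandin genes -0.01 ± 0.12 (camera adjusted p 0.784). Microglia markers were divided, with 3 of 7 above 0 and a mean of -0.03 ± 0.05 (camera adjusted p 0.659). Aif1, a marker of microglia, had -0.18 ± 0.09 (SD, n = 3). Over the alternatives its ratio ran from -0.39 to -0.01, the latter after median centring. Of the antigen presentation, complement and acute phase, lymphocyte and neutrophil lists, 2, 2, 1 and 1 genes were tested, too few for the list test.

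Genes of the stress response were likewise without a call. The stress axis peptides and receptors had a mean of 0.11 ± 0.07 (SD of pair means, camera adjusted p 0.406). Its member with the smallest unadjusted p, Oxt, the oxytocin gene, had 0.38 ± 0.50 (SD, n = 3) and a pair 2 value of 0.94 against 0.21 and -0.01, so that it was 0.10 without pair 2. Glucocorticoid response genes had a mean of 0.04 ± 0.07 (camera adjusted p 0.659), and their member Fkbp5, a chaperone of the glucocorticoid receptor, had -0.11 ± 0.20 (SD, n = 3). Heat shock genes had a mean of 0.05 ± 0.04 (camera adjusted p 0.659) and oxidative stress genes 0.04 ± 0.04 (0.659). Proteasome subunits had -0.01 ± 0.10 (0.784). Circadian clock genes had -0.03 ± 0.13 (0.659), with Csnk1d, a clock kinase gene, at -0.29 ± 0.09 (SD, n = 3). Csnk1d had opposite signs on the slides of pair 2 (-1.14 and 0.36) and of pair 3 (0.21 and -0.75). Cholesterol synthesis had 3 tested genes.

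Neuronal genes showed small means on either side of 0. Synaptic vesicle and release genes were above 0 in 5 of 11 cases, with a mean of -0.04 ± 0.11 (SD of pair means, camera adjusted p 0.659). Sv2a, a synaptic vesicle protein, had -0.35 ± 0.13 (SD, n = 3). Snap25, a protein of the release machinery, had -0.01 ± 0.08, with its sign turned under 5 alternatives. Both genes had opposite signs on the 2 slides of every pair. In pair 2 the slides had -1.71 and 0.72 for Sv2a, and -1.47 and 1.28 for Snap25. Glutamate receptor genes had a mean of -0.01 ± 0.03 and a median of 0.03 (camera adjusted p 0.843). Among them Grin2b, an NMDA receptor subunit, had -0.26 ± 0.07, and Dlg4, the postsynaptic scaffold PSD-95, had 0.27 ± 0.21 (SD, n = 3). Grin2b had opposite signs on the slides of pair 2 (-0.96 and 0.46) and of pair 3 (0.38 and -0.79). Dlg4 had opposite signs on the slides of pairs 1 and 2. GABA receptor genes were below 0 in 5 of 5 cases, with a mean of -0.07 ± 0.16 (camera adjusted p 0.526). Neuropeptide, opioid and pain genes had 0.05 ± 0.05 (0.526), monoamine genes -0.02 ± 0.14 and a median of 0.03 (0.945), and neurotrophin genes 0.02 ± 0.09 and a median of -0.03 (0.908). Excitatory neuron markers had -0.03 ± 0.11 (0.659) and inhibitory neuron markers -0.02 ± 0.02 (0.719).

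Markers of other cell types were sparse. Endothelial and pericyte markers had a mean of -0.02 ± 0.07 (SD of pair means, camera adjusted p 0.719). The meningeal fibroblast and collagen list had 3 tested genes, all above 0 in all 3 pairs. Its member Dcn, the matrix proteoglycan decorin, had 0.35 ± 0.14 (SD, n = 3), with an adjusted p of 0.029 in limma over the list alone. Astrocyte markers had 4 tested genes with a mean of -0.19 ± 0.23, and S100b, which lay in the first spot column, had -1.86 in pair 3 against 0.06 and 0.02 in the others. Reactive astrocyte, striatal neuron and choroid plexus lists had 4, 3 and 1 tested genes, and the blood list had 0. Gfap, Nr3c1, Crh, Tnf, Mbp, Penk and Hba-a1 had no probe with their name here.

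**Figure D2:**
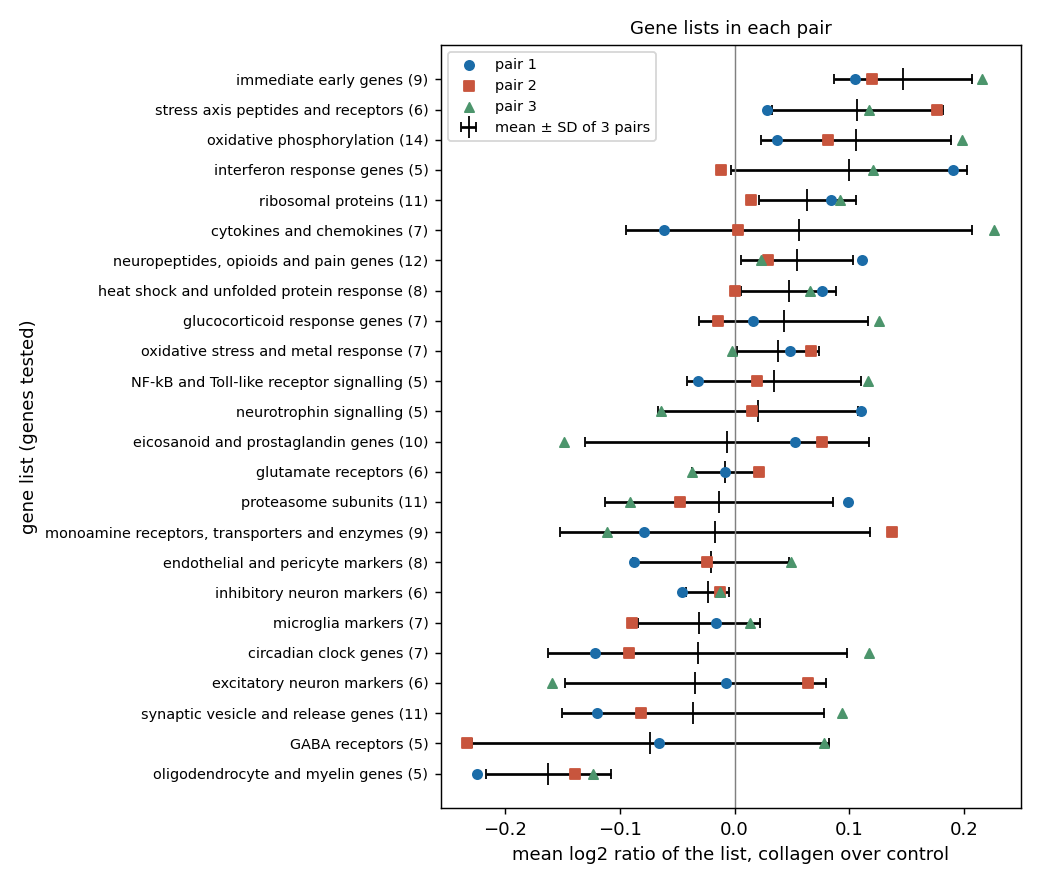
Mean log2 ratio of collagen over control (x axis) of the 24 gene lists with at least 5 tested genes (y axis, number of genes in brackets). Points are the 3 pairs and bars the mean ± SD. Immediate early genes are highest (0.15) and myelin genes lowest (-0.16), and no list passed the test.

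The third comparison asked how far slides and animals shared the same differences. Across genes, which are not independent replicates, the dye-averaged ratios of pairs 1 and 2 correlated at r = 0.20, those of pairs 1 and 3 at r = -0.10 and those of pairs 2 and 3 at r = -0.02. Both slides of a pair carried the same RNAs, yet their ratios turned to collagen over control correlated negatively, with r = -0.29 in pair 1, -0.58 in pair 2 and -0.23 in pair 3. In the authors' value table these correlations were -0.46, -0.54 and -0.36. Rescans of one slide correlated between 0.78 and 0.88.

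**Figure D3:**
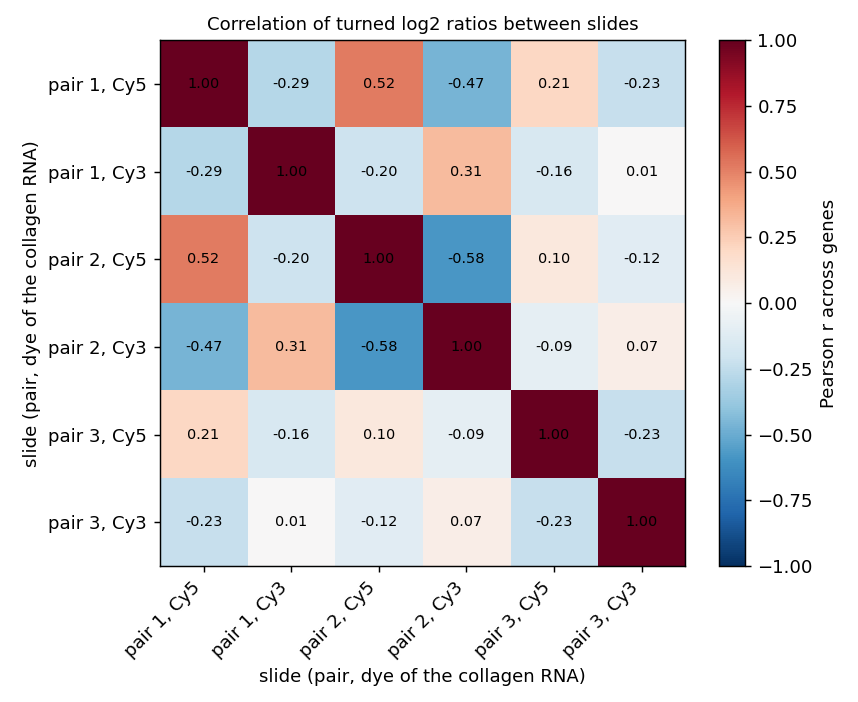
Pearson r across 4815 genes of log2 ratios turned to collagen over control, for each couple of the 6 slides (both axes: pair and dye of the collagen RNA). Slides of one pair are negatively correlated (-0.29, -0.58 and -0.23).

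The last comparison was between the channels, over both dye orientations. With the dyes as labelled, a difference between the arms cancels in it. A dye effect passed limma's test for 45 genes at an adjusted p under 0.05 (367 at an unadjusted p under 0.05), all 45 brighter in channel A. No gene passed with an intensity trend in the prior variance (0) or with ordinary one-sample statistics (0), and the count was 27 without pair 1 and 185 without pair 3. Krt14, a keratin gene, was 3.99-fold brighter in channel A than in channel B, Dbf4, a gene of DNA replication, 3.40-fold, and Nr4a3, an immediate early gene, 2.45-fold. Probes without a listed gene made up 42.2% of the 45 and 8.91% of all tested. In the first spot column, the pair 3 slide with collagen RNA in Cy5 had a median log2 ratio of -5.14 over 104 spots, against 0.55 over 79 spots on its partner slide.

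**Figure D4:**
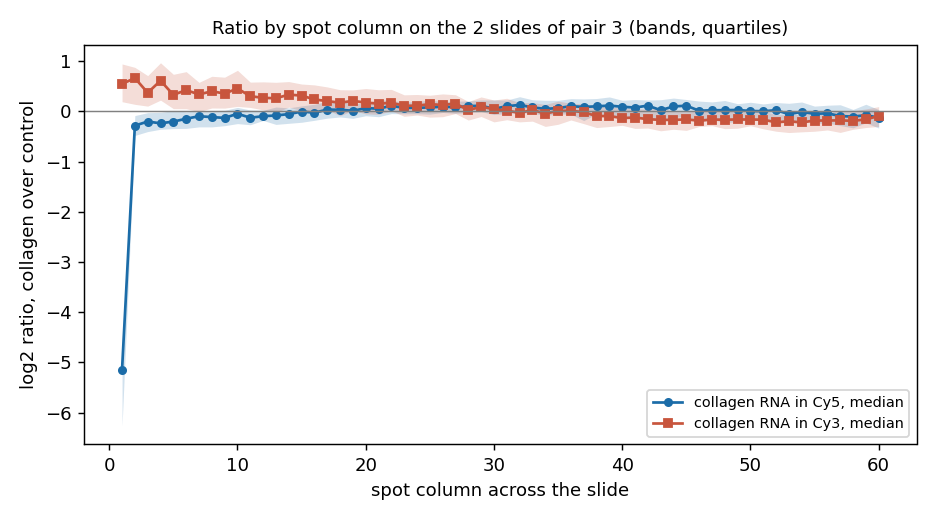
Median log2 ratio of collagen over control (y axis) by spot column across the slide (x axis) on both slides of pair 3, with bands from the lower to the upper quartile. The first column stands at -5.14 on the slide with collagen RNA in Cy5 and at 0.55 on its partner.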

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

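The tests of the channel effect, of exchanged RNAs and of the first spot column were chosen after the results were seen, while those of the sign choices were written before. Those of the immediate early genes were written after the list's place near the threshold was seen and before their own values were. The result singled out was the 45 genes whose collagen over control ratio differed between the 2 dye orientations in limma at an adjusted p under 0.05, a count that was 0 with an intensity trend in the prior variance and 0 with ordinary one-sample statistics.

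The first pattern is that the slides of one pair opposed each other after turning. An RNA difference between the arms, with the dyes as labelled, would give a positive correlation. The mean over the 3 pairs was -0.3671, with all 3 below 0. These are the same correlations that define the pattern, so they are not a separate test of it. A channel effect of the spots shared by all slides may account for the pattern: unturned ratios of slides of opposite orientation and different pairs correlated at a mean of 0.2115. For slides of the same orientation and different pairs the mean was 0.204. With the dyes as labelled, an arm difference shared by the pairs would make the same-orientation mean the higher of them, which it was not. Exchanged slides that in fact carried the RNAs in the same channels as their partners may also account for the pattern. Deviations from the orientation mean correlated positively within pairs, at a mean of 0.2209. A channel effect particular to the slides of a pair gives the same positive value, so the test does not separate these, and an exchange of dyes that failed would cancel real differences along with the dye effect.

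The second pattern is the low ratios of pair 3 in the first spot column, with a median of -5.14 on the log2 scale over 104 spots of 1 slide. An RNA difference of these genes would recur on the partner slide, whose median was 0.5476 (95% bootstrap interval 0.36 to 0.76), of opposite sign. A fault at the slide edge is a candidate explanation. On that slide the median intensity per pixel in the column was 14443 in channel A against 3227 elsewhere, and 179 in channel B against 2904. The partner slide has a gradual trend across its columns, so its own value is not free of position.

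The third pattern is the immediate early genes toward collagen. After loess, random lists matched on mean intensity had a median of 0.0038, and the list's median lay at percentile 99.99 of 10000 such lists. An intensity trend left after loess is thus argued against as the only source. The test cannot weigh a trend that loess had already removed, and the list was picked for standing near the threshold. After median centring, without loess, the list's camera adjusted p was 0.23. A channel effect equal on both slides of a pair cancels in the pair means, which were 0.11, 0.12 and 0.22, so it does not account for them. Whether an effect that differs between the slides of a pair could do so cannot be told apart from a shift of the list: the lower of the 2 orientation medians was -0.0703, with a 95% bootstrap interval over the genes from -0.52 to 0.04, which holds values on either side of 0. A response of cortical neurons to collagen immunisation remains open and untested as such.

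With 3 pairs there are 4 choices of sign, so no share under 0.05 can be reached. For the genes changed, the real choice gave 0 and the highest other 0, so that 4 of the 4 choices gave as many. For the gene lists the real choice gave 0 and the highest other 0, again 4 of 4. For the genes with a dye effect the real choice gave 45 and the highest other 0, so that 1 choice gave as many.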

How the results depend on the processing

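The alternatives with normexp, without the first spot column and with genes measured in at least 2 pairs, and those of the dye effect other than median centring and leaving out pairs, were chosen after seeing the data. Of 34 named genes, 32 kept their direction wherever they had a value, and 8 of 628 combinations of gene and alternative turned, all of Snap25 or Il1b. Many could not: filters, variance models and blocks leave ratios unchanged, and genes of one sign on all 6 slides keep it without a pair. Snap25 had a log2 ratio of 0.0050 without background correction, 0.032 after scaling between slides, 0.012 on the last scan, 0.045 in the authors' value table and from -0.042 to 0.035 with 1 pair left out. Il1b had -0.015 after print-tip loess, -0.0031 in the value table and from -0.060 to 0.149 with 1 pair left out. The cause of these turns was not tested. With normexp 23 of the 34 were over 1.5 times larger, Foxp3 at 1.06 and Top1 at 1.08 among them. Over 1.5 times smaller were 9 of 34 without background correction (Foxp3 at 0.16), 6 after print-tip loess, 6 without pair 2 (Oxt at 0.10) and 11 of 19 in the value table, whose scale is unknown. Each other alternative moved at most 7 of them over 1.5 times either way.

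The count of genes changed stayed at 0 except in the value table (2 of 3142, Wdr82 and Map1b) and when a pair was left out, from 0 to 40. The highest count, without pair 2, held 33 genes of the first spot column. The 14 without pair 3 included Wdr82 and Rita1, the only 2 of them with one sign on all 6 slides. Rbbp5 and Has3, also among the 14, were among the genes with a dye effect. The count was 0 with no replicate block (6 slides taken as independent) and 0 with the block as a random effect and a dye term. Neither changed a call of a list. The count of gene lists was 1 without background correction (myelin, down), 1 after print-tip loess and 1 after scaling between slides (immediate early genes, up), 2 with an intensity trend in the prior variance (immediate early genes and oxidative phosphorylation, up) and 2 without the first spot column (immediate early genes up, myelin down). It was 0 under the other alternatives, leaving out each pair included. Over all alternatives run the camera adjusted p ran from 0.0105 to 0.824 for immediate early genes and from 0.0435 to 0.824 for oxidative phosphorylation. For myelin genes it ran from 0.0212 to 0.824, with no test on only the first scan or in the value table, where fewer lists were tested (16 and 14). The mean correlation between pairs was 0.03 and ran from -0.10 to 0.20 with 1 pair left out.

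The dye effect, found for 45 genes, depended on the variance model: 0 genes passed with an intensity trend in the prior variance and 0 with ordinary one-sample statistics. It was 71 without the first spot column, 71 with the replicate block as a random effect, 97 with values in at least 2 pairs, 19 in the value table and from 27 to 185 with 1 pair left out. The cause of these moves was not tested. Dropping the filter on dim spots removed no tested gene, so it shows nothing, and plain subtraction of background is the setting used. The lowest median signal over background was 0.893, in channel A of 1 slide of pair 2, which still kept 9670 spots. The spots without an accepted signal, which left 6911 on 1 slide of pair 3, limit which genes could be tested.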

Other observations

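Immediate early genes and oxidative phosphorylation genes both stood high against random lists of equal intensity, at percentiles 99.99 and 99.97 of 10000 lists, while the myelin genes' median stood at percentile 12.7. Orientation medians of the oxidative phosphorylation list were 0.23 on slides with collagen RNA in Cy5 and 0.00 with collagen RNA in Cy3. The lists were picked after they were seen to stand nearest to the threshold. For the immediate early genes the bound on the percentile was written before it was computed, and for the other lists none was written.

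Some list genes had a value in only 2 pairs and were not among the 4815 genes tested, but they did enter the alternative with values in at least 2 pairs. Among them Sc5d, an enzyme of cholesterol synthesis, had a log2 ratio of -0.49, Irak1, a kinase of Toll-like receptor signalling, 0.39, and Acsbg1, an astrocyte marker, 0.43. The cytokine gene Il6 had -0.38, the chemokine gene Ccl2 0.26, and Sst, the somatostatin gene, 0.31. None passed in limma over 7810 genes (adjusted p 0.961 each). These genes were picked after their values were seen.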
